A study of Mus musculus with 40 samples.

How the data were processed

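Expression was measured in the dentate gyrus of 40 mice, 1 array per animal: 37 labelled mutant for alpha-CaMKII, the kinase subunit encoded by Camk2a, and 3 labelled wild type. The labels also give each animal's age (22 to 33 weeks) and a 24-h LA value, read here as activity over 24 h, whose unit is not given in the sources used here. Total RNA was labelled with biotin and hybridised to Affymetrix mouse arrays. The deposited values are log2 RMA values per probe set, made by the authors and credited to RMA in the submitters' processing notes, with no version given. RMA corrects background, normalises between arrays and summarises probes. The log2 scale was checked on the values, which ran from 1.67 to 13.98 over 45101 probe sets with 0 missing values. Dates of dissection and hybridisation, the hour at which tissue was taken, the sex of the animals and any exclusion of samples are not given in the sources used here. The number of arrays limits the precision of each estimate. The limma p-values were computed from the spread between these samples, pooled over the compared groups.

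Of the probe sets, 64 are array controls. The annotation lists 35890 probe sets, of which 34958 name 1 gene and 932 name several, and 9211 probe sets had no gene listed. Single-gene probe sets were matched by gene ID to a current list of genes, which matched 34754 and left 204 with the symbol given for the array. The match changed 0 symbols. Each gene was represented by its probe set with the highest mean over all arrays, which gave 18194 genes, with no filter on dim genes. Values were analysed as deposited. The files name no genome build, so no coordinates are given, and the order of genes along chromosomes was taken from assembly GRCm38.p6 only to find neighbours of Camk2a.

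Each comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05), with values read by version 1.17.8 of data.table. Genotype was compared over all 40 arrays without other terms, and again with the log2 of the 24-h activity in the model, called matched activity below. Among the 37 mutants, the slope on log2 activity gives a log2 change per doubling of activity. The log2 activity of the mutants has 1 widest gap, between 25590.06 and 41603.46, a ratio of 1.63 where the next largest ratio between neighbours is 1.19. It leaves 16 lower-activity and 21 higher-activity mutants, so slopes within each side and the contrast of the sides were also fitted, and no correlation is pooled across the gap. The slope per week of age was fitted with log2 activity in the model.

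A set of 30 gene lists with 555 members was fixed, of which 498 places (484 different genes) were measured as single genes, and members without such a probe set were not analysed here. The lists cover clock genes, immediate-early genes, later activity-responsive genes, mature granule cell markers, immature neuron markers, proliferation, CaMK and calcium signalling, cAMP signalling, glutamate, GABA and monoamine receptors, ion channels and neuropeptides. They also cover markers of interneurons, CA pyramidal neurons, thalamus, choroid plexus, astrocytes, oligodendrocytes, their precursors, microglia, endothelium, mural and meningeal cells and blood, as well as glucocorticoid-responsive genes, heat shock genes, respiratory chain subunits, glycolysis, ribosomal proteins and synaptic vesicle genes. Some genes sit in 2 lists, such as Pcp4, Drd1, Adcy1 and Pde4b, and many list genes are also expressed by granule cells. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists, beside camera with an estimated correlation and fry. Activity was predicted for each mutant from the expression of the other mutants by ridge regression on all genes with the penalty equal to the number of genes, against 100 permutations. Single values were compared by 2-sided permutation tests, exact where all regroupings could be listed and otherwise with 1e+05 draws.

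The named genes followed a rule. Camk2a came first. For the genotype, matched-activity and activity comparisons, up to 8 genes per direction with the largest change were named among genes past the threshold whose mean was among the 9097 highest, skipping symbols of uncharacterised clones. From each list with a call or at least 3 members past the threshold up to 4 members were named, and from each list with none up to 2, given as values. The rule left open lists with 1 or 2 members past the threshold and no call, and there the members past the threshold were named. Calb1, Tdo2, Dsp, Calb2, Drd1 and Dcx, which mark the maturation of granule cells, were named whatever their values. The groups, the comparisons, the lists, the rule and the first set of alternatives were chosen before the data were examined.

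The steps were tested on simulated data with 18194 genes each. In the genotype comparison 85% of genes changed by 0.5 and 100% of genes changed by 1 log2 unit were recovered, with 9 false calls among 194. At matched activity the shares were 73% and 99%, with 7 false calls among 179. For activity, 68% of genes with a slope of 0.1 and 97% with a slope of 0.2 were recovered, with 3 false calls among 168. For age, 31% of genes with a slope of 0.02 and 91% with a slope of 0.05 per week were recovered, with 6 false calls among 128. The simulated values held no differences between runs and no array with a doubtful label, and genes varied independently. These rates are therefore those of simpler data and need not hold for the real arrays.

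The array labelled mutant 27 and the array labelled wild type 3 each carried the Camk2a level of the other group. All 40 arrays were analysed under their labels. An alternative chosen after seeing the data leaves out both arrays, and no array was moved to another group. Other alternatives for the values were quantile normalisation, centring on array medians, the mean of a gene's probe sets, all probe sets, and only the 9097 genes with the higher means. Alternatives for the fit were limma's arrayWeights, eBayes with trend and robust options, age as a covariate, runs of 8 samples in accession order as a block, and a threshold of 0.01. Further ones were only the lower-activity mutants against wild type, other scales of activity, other penalties, and leaving out each animal. The runs of 8 stand in for processing batches, which the labels do not name. List tests for age and a list of cholesterol synthesis genes were added after the data were seen. The place of the Camk2a probe sets relative to the mutation is not given in the sources used here.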

Results

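Gene expression was measured in the dentate gyrus, the hippocampal field made mostly of granule cells, of 37 mice labelled mutant for alpha-CaMKII and 3 mice labelled wild type, on 1 array each. The series asks which genes differ between the genotypes and which follow the activity of the animal. The 24-h activity of the mutants ran from 16273.92 to 128827.08 with a median of 46297.38, and that of the wild types from 14301.12 to 20979.78. All 3 wild types and 16 mutants therefore lay below the widest gap in activity, and the other 21 mutants lay above it. No relation of age to log2 activity was detected within either side. Within the lower side Pearson's r was 0.101 (permutation p = 0.713, adjusted p = 0.713, r = -0.448 without the 2 farthest animals) and Spearman's rho was 0 (permutation p = 1). Within the higher side r was -0.201 (permutation p = 0.382, adjusted p = 0.713, r = -0.112 without the 2 farthest) and rho was -0.274 (permutation p = 0.228, adjusted p = 0.455).

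The targeted gene, Camk2a, encodes the alpha subunit of calcium/calmodulin-dependent kinase II, an abundant synaptic kinase. The brightest of its 6 probe sets averaged 12.16 ± 0.14 (SD, n = 37) in mutants and 12.56 ± 0.42 (SD, n = 3) in wild types, a log2 difference of -0.40 (SE 0.10, adjusted p = 0.014, lower than the wild-type mean in 36 of 37 mutants). The arrays labelled wild type 1 and 2 read 12.79 and 12.81. The array labelled wild type 3 read 12.08, where the other 36 mutants averaged 12.14 ± 0.06 and reached at most 12.31. The array labelled mutant 27 read 12.90, above wild types 1 and 2. Without these 2 arrays, left out and not exchanged, the difference was -0.66 (SE 0.06, adjusted p = 4.1e-11 over probe sets). Of the 5 dimmer Camk2a probe sets, that with a mean of 7.48 in mutants fell by 0.67 (SE 0.19, adjusted p = 0.048 over probe sets). Those with means of 9.58 (-0.70, SE 0.21, adjusted p = 0.075), 5.76 (-0.71, adjusted p = 0.163), 8.0 (-0.45, adjusted p = 0.468) and 5.29 (-0.077, SE 0.14, adjusted p = 0.909) did not pass. Without the 2 arrays, those at 9.58 (-1.18, adjusted p = 1.2e-05), 7.48 (-0.96, adjusted p = 1.4e-05) and 5.76 (-0.96, adjusted p = 0.0093) passed. Those at 8.0 (-0.58, adjusted p = 0.090) and 5.29 (-0.17, adjusted p = 0.595) did not.

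**Figure D1:**
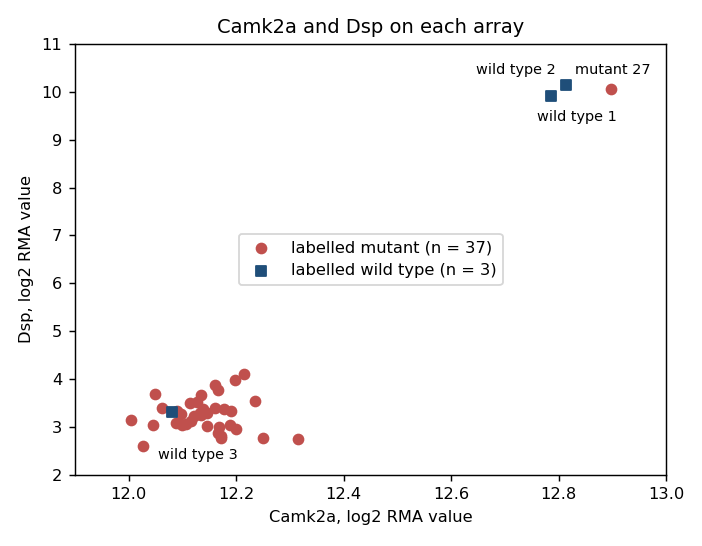
Camk2a (brightest probe set, log2 RMA value) against Dsp (log2 RMA value) on each of the 40 arrays, coloured by the group in the label. The array labelled mutant 27 (Camk2a 12.90) lies beside wild types 1 and 2, and the array labelled wild type 3 (Camk2a 12.08) lies among the other 36 mutants.

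Any 2 arrays correlated at 0.983 to 0.998 over genes, which are not independent replicates, and no array duplicated another (smallest SD of a difference 0.153, median 0.249). The first principal component held 27.2% of the variance, and 95.0% of it lay between runs of 8 consecutive samples. The second component held 13.4%, with 5.93% of it between runs. On it wild types 1 and 2 lay at -34.4 and -34.2 and the array labelled mutant 27 at -32.95. The array labelled wild type 3 lay at 2.88, within the range of the other mutants (-4.18 to 10.03). The components were computed without the labels. Array medians were 4.84 to 4.87 in the first run and 4.89 to 4.94 in the others, and 10973 genes differed between runs among the mutants. The 3'-to-5' difference of the actin control probe sets, a measure of RNA degradation, averaged 1.04 in the first run and from 1.43 to 1.57 in the others. It was 1.41 ± 0.19 (SD) in mutants and 1.33 ± 0.28 in wild types (exact permutation p = 0.513, adjusted p = 0.551), and that of Gapdh was 0.372 and 0.344 (exact permutation p = 0.551). Higher-activity and lower-activity mutants differed in neither (actin -0.057, permutation p = 0.378, and Gapdh 0.385 against 0.356, permutation p = 0.268, both adjusted p = 0.551). Each run of 8 held mutants, while the wild types lay 1 each in runs 1, 2 and 4. Without the arrays labelled mutant 27 and wild type 3, wild types remain in runs 1 and 2 only. Genotype gene counts are given with the runs as a block below. The genotype list tests and list means were not fitted with that block.

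Several markers of mature granule cells fell far in mutants. Dsp, which encodes the junction protein desmoplakin of mature granule cells, fell from 7.79 ± 3.88 (SD, n = 3) in wild types to 3.44 ± 1.17 (SD, n = 37) in mutants, a log2 change of -4.35 (SE 0.82, adjusted p = 0.0033). It lay below the wild-type mean in 36 of 37 mutants. SEs and limma p-values of this comparison use 1 spread per gene pooled over both groups, to which the 37 mutants contribute most. Where the 3 wild types spread more, as for Dsp, the SE understates the uncertainty of the wild-type mean. Tdo2, the tryptophan dioxygenase of mature granule cells, fell from 6.58 ± 3.48 to 2.98 ± 0.94 (-3.59, SE 0.69, adjusted p = 0.0033). Calb1, the calcium buffer calbindin, fell from 10.89 ± 1.11 to 9.65 ± 0.39 (-1.24, SE 0.26, adjusted p = 0.0051). The dopamine receptor gene Drd1 rose from 7.42 ± 1.33 to 8.76 ± 0.37 (1.34, SE 0.27, adjusted p = 0.0038). Penk, the precursor of enkephalin, rose from 8.43 ± 1.48 to 10.08 ± 0.54 (1.65, SE 0.35, adjusted p = 0.0055). Calb2 (0.14, SE 0.16, adjusted p = 0.786) and Dcx (0.31, SE 0.19, adjusted p = 0.492), markers of young neurons, did not pass.

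In all, 719 of 18194 genes differed between mutant and wild type, 370 higher and 349 lower, and 2721 had an unadjusted p under 0.05. The count depended on which wild types were kept, with 0 genes past the limma threshold without wild type 1 (956 unadjusted) and 0 without wild type 2 (1744 unadjusted). Both of these fits kept the array labelled wild type 3, with the Camk2a level of the mutants, as 1 of only 2 wild types. Without that array instead, 2360 genes passed. Of the 719, 440 genes had several probe sets, and 0 genes had probe sets past the limma threshold in both directions. The largest rises among well-expressed genes were those of Arr3 (1.75, SE 0.38, adjusted p = 0.0061), the transcription factor Nhlh1 (1.66, SE 0.39, adjusted p = 0.0095), Penk (above) and the axon guidance receptor Robo3 (1.55). Next came the receptor partner Ramp3 (1.53), the kinase Wnk4 (1.46), the copine Cpne9 (1.44) and the potassium channel Kcnt2 (1.44). The largest falls among well-expressed genes were those of the cell death gene Hrk (-1.50, SE 0.27, adjusted p = 0.0033), Marcksl1 (-1.45, SE 0.34, adjusted p = 0.0088) and the transcription factor Cebpd (-1.35, SE 0.26, adjusted p = 0.0033). Next came Spon1 (-1.32), Rreb1 (-1.26), Calb1, the AMPA receptor partner Cnih3 (-1.17) and the growth factor receptor Gfra2 (-1.17). In each of these 16 genes the array labelled mutant 27 lay nearer to wild types 1 and 2, and the array labelled wild type 3 nearer to the mean of the other mutants. All 36 other mutants lay beyond wild types 1 and 2 in the direction of the change. Without both arrays 2604 genes differed (1102 higher, 1502 lower), among them 718 of the 719 in the same direction. With runs of 8 as a block 1363 genes differed (671 higher, 692 lower), and without the 2 arrays and with the block 3631 (1610 higher, 2021 lower). Without both arrays the change was -6.77 (SE 0.25) for Dsp, -5.75 (SE 0.17) for Tdo2, -1.93 for Calb1, 2.15 for Drd1 and 2.59 for Penk.

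Among 15 mature granule cell markers, 2 rose, 6 fell and 7 did not pass, and 4 rose and 7 fell when adjusted over the list alone. Besides Dsp, Tdo2 and Calb1, the interleukin receptor Il1r1 (-1.57, SE 0.35, adjusted p = 0.0071), the scaffold gene Tanc1 (-0.31) and Lct (-0.44) fell. The polo-like kinase Plk5 (0.98, SE 0.22, adjusted p = 0.0071) and the adenylyl cyclase Adcy1 (0.29, SE 0.07, adjusted p = 0.015) rose. The list as a whole was lower than other genes (median -0.18, mean -0.70, camera adjusted p = 0.016, adjusted p = 0.319 with an estimated correlation). Of 15 immature neuron markers 2 rose, Drd1 and Neurod1 (0.30, SE 0.09, adjusted p = 0.045), and 13 did not pass. The counts were the same when adjusted over the list alone (median 0.14, camera adjusted p = 0.032, adjusted p = 0.407 with an estimated correlation). Stmn1 (-0.16, adjusted p = 0.209) and Igfbpl1 (0.48, adjusted p = 0.345) did not pass. Of 15 proliferation genes Mcm6, a replication helicase subunit, fell (-0.77, SE 0.17, adjusted p = 0.0074) and 14 did not pass, with 1 down when adjusted over the list alone. That list did not shift (camera adjusted p = 0.897), its median of -0.02 and mean of -0.019 lying below 0 and its test statistic above 0.

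**Figure D2:**
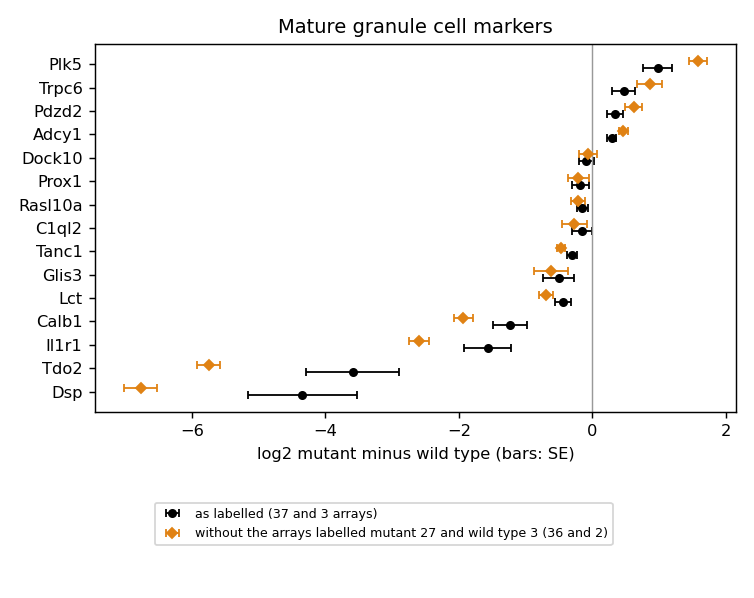
Log2 difference (mutant minus wild type, with SE) of 15 mature granule cell markers, as labelled (37 mutants and 3 wild types) and without the arrays labelled mutant 27 and wild type 3. Dsp, Tdo2 and Il1r1 lie farthest below 0 (-4.35, -3.59 and -1.57 as labelled), and Plk5 lies above it at 0.98.

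Some genes that follow neuronal activity rose in mutants. Of 21 immediate-early genes, which are switched on by neuronal firing, 5 rose, 0 fell and 16 did not pass in limma. When adjusted over the list alone 6 rose and 0 fell (median 0.082, camera adjusted p = 0.0018, adjusted p = 0.015 with an estimated correlation). Without the arrays labelled mutant 27 and wild type 3, 7 rose and 2 fell, with a median of 0.030 (camera adjusted p = 0.0016). Egr1 rose by 0.90 (SE 0.16, adjusted p = 0.0033), and Fosl2 by 0.69 (SE 0.17, adjusted p = 0.016). Dusp1 rose by 0.37 (SE 0.11, adjusted p = 0.037) and Nr4a3 by 0.31 (SE 0.09, adjusted p = 0.039). Of 22 later activity-responsive genes 6 rose, 1 fell and 15 did not pass. When adjusted over the list alone 8 rose and 3 fell (median 0.12, camera adjusted p = 0.0058, adjusted p = 0.180 with an estimated correlation). Nptx2, a synaptic pentraxin, rose by 1.31 (SE 0.25, adjusted p = 0.0033), the sorting receptor Sorcs3 by 1.02 (SE 0.23, adjusted p = 0.0077) and Acvr1c by 0.98 (SE 0.22, adjusted p = 0.0073). The phosphatase Dusp4 fell by 0.66 (SE 0.14, adjusted p = 0.0058).

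Camk4, Camk1d and Camkk2 rose while Camk2a fell, and Camk2b (-0.19, adjusted p = 0.544), Camk2d, Camk2g, Camk1 and Camk1g did not pass. Of 17 genes of CaMK and calcium signalling 5 rose, 2 fell and 10 did not pass. When adjusted over the list alone 6 rose and 3 fell (median 0.077, camera adjusted p = 0.017, adjusted p = 0.0498 with an estimated correlation). Camk4 rose by 0.97 (SE 0.19, adjusted p = 0.0033), and Camk1d by 0.65 (SE 0.11, adjusted p = 0.0031). Their activating kinase Camkk2 rose by 0.60 (SE 0.15, adjusted p = 0.011) and the calmodulin-binding protein neurogranin (Nrgn) by 0.44 (SE 0.09, adjusted p = 0.0055). Pcp4, another such protein, fell by 0.41 (SE 0.11, adjusted p = 0.021). Of 27 genes of cAMP signalling 3 rose, 0 fell and 24 did not pass in limma. When adjusted over the list alone 6 rose and 0 fell (median 0.058, camera adjusted p = 0.012, adjusted p = 0.0498 with an estimated correlation). These were the adenylyl cyclases Adcy8 (0.66, SE 0.14, adjusted p = 0.0055) and Adcy1 and the phosphodiesterase Pde4b (0.28, SE 0.08, adjusted p = 0.046). The kinase subunit Prkar2b did not pass (0.37, adjusted p = 0.076).

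Of 19 neuropeptide genes 4 rose, 0 fell and 15 did not pass in limma. When adjusted over the list alone 5 rose and 0 fell (median 0.028, camera adjusted p = 0.016, adjusted p = 0.407 with an estimated correlation). Without the 2 arrays 5 rose and 1 fell, with a median of -0.054 and a test above 0 (camera adjusted p = 0.0011, adjusted p = 0.184 with an estimated correlation). Besides Penk, the genes for gastrin-releasing peptide (Grp, 1.36, SE 0.27, adjusted p = 0.0038), galanin (Gal, 0.82, SE 0.20, adjusted p = 0.010) and dynorphin (Pdyn, 0.48, SE 0.14, adjusted p = 0.040) rose. Receptor and channel lists did not shift as a whole. Of 20 glutamate receptor genes Grm8 (0.66, SE 0.17, adjusted p = 0.018) and Grik4 (0.26) rose, Gria1 (-0.33, SE 0.10, adjusted p = 0.038) fell and 17 did not pass, with the same counts adjusted over the list alone. The median of that list was -0.025, its mean 0.029 and its test above 0 (camera adjusted p = 0.624). Of 10 GABA receptor genes Gabrd rose (0.48, SE 0.14, adjusted p = 0.037) and 9 did not pass, with 1 up adjusted over the list alone (camera adjusted p = 0.624). Of 14 monoamine receptor genes Drd1 rose, Htr1a fell (-0.89, SE 0.22, adjusted p = 0.014) and 12 did not pass, as when adjusted over the list alone. Its median was -0.0040, its mean 0.066 and its test above 0 (camera adjusted p = 0.665). Of 27 ion channel genes Scn3b fell (-0.55, SE 0.15, adjusted p = 0.026) and 26 did not pass, with 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.293). Without the 2 arrays 8 ion channel genes rose and 4 fell (camera adjusted p = 0.079). Of 22 synaptic vesicle genes 0 passed, alone or over all genes (limma; camera adjusted p = 0.231), Doc2b (-0.55, adjusted p = 0.055) and Rims1 (0.15, adjusted p = 0.137) coming closest.

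Markers of microglia were lower as a group, although 0 of 14 passed singly over all genes or when adjusted over the list alone (limma; median -0.18, camera adjusted p = 0.0030, adjusted p = 0.319 with an estimated correlation). Siglech (-0.31, adjusted p = 0.122), P2ry12 (-0.26, adjusted p = 0.171), Aif1 (-0.25) and Csf1r (-0.20) had the smallest p. Without the arrays labelled mutant 27 and wild type 3, 7 of the 14 fell, Siglech by 0.51 (adjusted p = 0.0025). Of 13 CA pyramidal neuron markers Necab2 rose (0.76, SE 0.21, adjusted p = 0.032), Iyd (-1.08, SE 0.26, adjusted p = 0.012), Rgs14 (-0.63, SE 0.16, adjusted p = 0.018) and Pcp4 fell and 9 did not pass. There were 1 up and 4 down adjusted over the list alone (median -0.36, camera adjusted p = 0.070). Without the 2 arrays that list was lower as a group (median -0.61, camera adjusted p = 0.012, adjusted p = 0.339 with an estimated correlation). Of 12 thalamic markers Ramp3 rose and 11 did not pass, with 1 up adjusted over the list alone (camera adjusted p = 0.114). No member passed among markers of interneurons (Gad1 -0.26, camera adjusted p = 0.654 for the list), astrocytes (Gja1 -0.11, camera adjusted p = 0.740) and oligodendrocytes (Opalin -0.22, camera adjusted p = 0.665). The same held for oligodendrocyte precursors (Pdgfra -0.11, camera adjusted p = 0.883), endothelium (Cdh5 -0.22, camera adjusted p = 0.352) and mural and meningeal cells (Lum -1.03, camera adjusted p = 0.665). It also held for choroid plexus (Kl -1.10, camera adjusted p = 0.897) and blood (Hba-a2 -0.24, camera adjusted p = 0.885). Adjusted over the list alone 1 mural and meningeal marker fell and no other member of these 8 lists passed. Without the 2 arrays, over all genes, Gad1 (-0.44, adjusted p = 0.0022), Lum (-1.76, adjusted p = 4.4e-05), Kl (-1.76, adjusted p = 0.010) and Hba-a2 (-0.44, adjusted p = 0.034) fell. No other member of these lists passed there. Medians and means differed in sign for choroid plexus (0.0059 and -0.092), precursors (0.031 and -0.032) and astrocytes (-0.011 and 0.0093), and the test followed the mean.

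Of 14 glycolysis genes Pfkp (0.42, SE 0.09, adjusted p = 0.0069) and Ldha (0.24, SE 0.06, adjusted p = 0.012) rose and 12 did not pass. There were 3 up adjusted over the list alone (median 0.040, camera adjusted p = 0.016, adjusted p = 0.467 with an estimated correlation). Ribosomal protein genes were lower as a group, with 0 of 18 past the limma threshold over all genes or when adjusted over the list alone (median -0.066, camera adjusted p = 0.016, adjusted p = 0.761 with an estimated correlation), Rps2 being nearest (-0.22, adjusted p = 0.069). Of 17 glucocorticoid-responsive genes Cdkn1a rose (0.67, SE 0.16, adjusted p = 0.0092) and 16 did not pass, as when adjusted over the list alone (camera adjusted p = 0.665). Respiratory chain subunits (Cox5b -0.074, camera adjusted p = 0.765) and heat shock genes (Xbp1 0.15, camera adjusted p = 0.665) did not shift, and 0 members passed in limma, also adjusted over the list alone. The median of heat shock genes was 0.019 and their test above 0, with a mean of -0.0032. Of 22 clock genes 0 passed over all genes, and 1 was higher when adjusted over the list alone (limma, with camera adjusted p = 0.223), Npas2 coming nearest (0.44, adjusted p = 0.053). Without the arrays labelled mutant 27 and wild type 3, 4 clock genes rose, Npas2 among them (0.75, adjusted p = 4.9e-05), and 1 fell (camera adjusted p = 0.105). In all 10 of 30 lists shifted, 7 up and 3 down, 3 of them with an estimated correlation and 6 with fry. Without the 2 arrays 11 shifted, 5 of them with an estimated correlation. The count was 6 without wild type 1, 1 without wild type 2 and 8 without the array labelled wild type 3. Of 100 regroupings of the arrays 7 gave as many lists, so chance was not excluded.

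Because the wild types were all of low activity, the genotype was also compared at matched activity, and the granule cell changes held their size. Dsp fell by 4.55 (SE 0.87, adjusted p = 0.0050), Tdo2 by 3.55 (SE 0.74, adjusted p = 0.0061), Calb1 by 1.26 (SE 0.28, adjusted p = 0.0079) and Camk2a by 0.45 (SE 0.10, adjusted p = 0.0099). Penk rose by 1.77 (SE 0.37, adjusted p = 0.0065), Grp by 1.42 (SE 0.29, adjusted p = 0.0061) and Drd1 by 1.40 (SE 0.29, adjusted p = 0.0059). In all 654 genes differed, 339 higher and 315 lower (2646 with an unadjusted p under 0.05), and 583 of them were also among the 719, all in the same direction. Without the arrays labelled mutant 27 and wild type 3, 2477 differed, among them all 654. The count was 0 in limma without wild type 1 (908 unadjusted), 1 without wild type 2 and 2243 without the array labelled wild type 3. Genes named here beyond those above were Ccbe1 (-1.16, SE 0.30, adjusted p = 0.021) and the CA marker Cacng5 (-0.83, SE 0.25, adjusted p = 0.049). The clock output regulator Nfil3 (-0.36, SE 0.10, adjusted p = 0.035) was another. The stress gene Xbp1, named above without passing, passed here (0.21, SE 0.063, adjusted p = 0.048). Immediate-early genes were again higher as a group, 4 up and 0 down of 21 in limma. Adjusted over the list alone 6 were up (camera adjusted p = 2.5e-04, adjusted p = 0.0019 with an estimated correlation). In all 8 lists shifted, 5 up and 3 down, and 1 did so with an estimated correlation.

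The next comparison asked which genes follow the activity of the animal, among mutants alone. The clock gene Arntl, whose protein drives the daily rhythm of transcription, rose with activity, by 0.14 log2 units per doubling (SE 0.022, adjusted p = 8.6e-04). It averaged 7.79 ± 0.12 (SD, n = 16) in lower-activity and 8.07 ± 0.15 (SD, n = 21) in higher-activity mutants, 20 of 21 of which lay above the lower side's median. Id4, a regulator of neural precursors and astrocytes, fell with activity by 0.13 per doubling (SE 0.021, adjusted p = 8.6e-04), from 10.49 ± 0.09 to 10.27 ± 0.17. Among genes past the threshold the transcription factor Batf3 fell most (-0.20, SE 0.040, adjusted p = 0.017), from 6.58 ± 0.19 to 6.16 ± 0.28. It lay below the lower side's median in 21 of 21 higher-activity mutants.

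In all 12 of 18194 genes varied with activity, 6 up and 6 down, and 1022 had an unadjusted p under 0.05. The others that rose were the linker histone gene H1f2 (0.16, SE 0.024, adjusted p = 8.6e-04), the protease inhibitor Timp4 (0.13, SE 0.027, adjusted p = 0.023) and the actin regulator Fam107a (0.12, SE 0.019, adjusted p = 8.6e-04). Acot11 rose as well (0.12, SE 0.020, adjusted p = 0.0027), and so did Cenpw (0.15, SE 0.031, adjusted p = 0.036), a dimmer gene outside the naming rule and chosen after its value was seen. The others that fell were the ciliary gene Cys1 (-0.14, SE 0.023, adjusted p = 8.6e-04), and the adenylate kinase Ak4 (-0.13, SE 0.022, adjusted p = 0.0027). They also held the endothelin receptor Ednrb (-0.12, SE 0.024, adjusted p = 0.018) and Lonrf1 (-0.091, SE 0.016, adjusted p = 0.0034). With runs of 8 as a block 44 genes varied, and without the array labelled mutant 27 26 did, each time among them all 12. None of the fixed granule cell genes passed with activity, neither Camk2a (0.035, SE 0.023, adjusted p = 0.969) nor Calb1 (0.0044), Tdo2 (-0.083), Dsp (0.11), Calb2 (-0.023), Drd1 (-0.033) or Dcx (-0.068). This fit includes the array labelled mutant 27, which widens the spread of Camk2a, and none of these genes passed without it either. Camk2a lay above the lower side's median in 19 of 21 higher-activity mutants, so a small rise is not excluded.

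**Figure D3:**
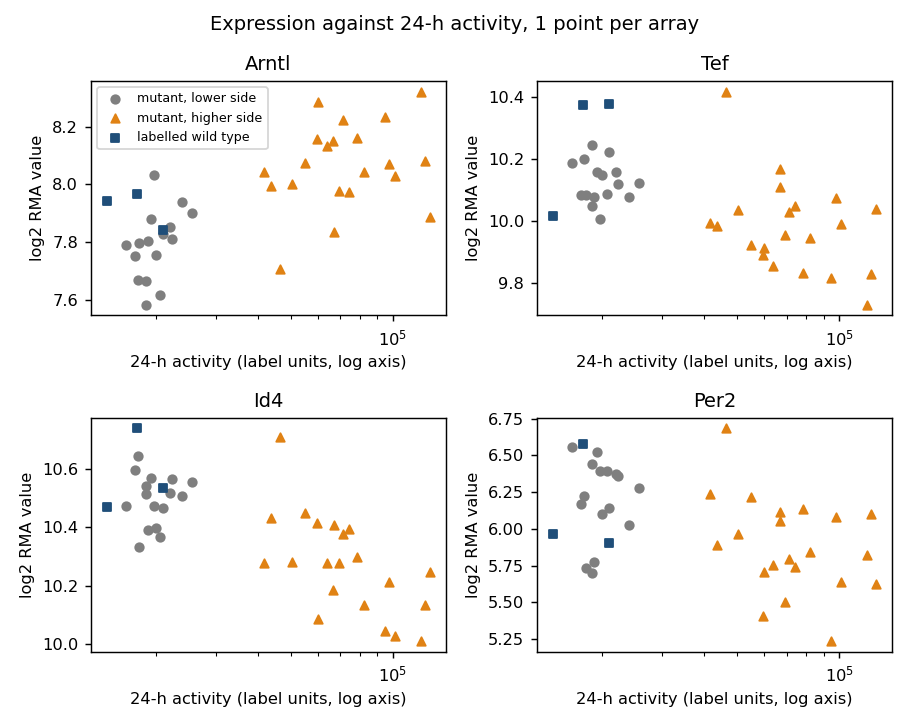
Log2 RMA values of Arntl, Tef, Id4 and Per2 against the 24-h activity of each animal (log axis, in the units of the labels), for 16 lower-activity mutants, 21 higher-activity mutants and 3 arrays labelled wild type. Arntl rises (0.14 per doubling) and Id4 falls (-0.13 per doubling). Tef (-0.084, adjusted p = 0.088) and Per2 (-0.18, adjusted p = 0.235) did not pass.

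The clock list held 1 gene up and 0 down over all genes, Arntl, and 3 up and 6 down when adjusted over the list alone. Its members went both ways (fry test for change in either direction, adjusted p = 0.0050), and the list did not shift as a whole (median -0.028, camera adjusted p = 0.051, adjusted p = 0.198 with an estimated correlation). Tef (-0.084, SE 0.019, adjusted p = 0.088), Ciart (-0.16, SE 0.041, adjusted p = 0.199), Per2 (-0.18, SE 0.046, adjusted p = 0.235) and Dbp (-0.12, SE 0.033, adjusted p = 0.312), which the Arntl protein activates, did not pass over all genes. Tef passed without the array labelled mutant 27 (adjusted p = 0.0125). Immature neuron markers were lower with activity as a group (median -0.045, camera adjusted p = 0.0029, adjusted p = 0.198 with an estimated correlation). So were heat shock genes (median -0.020, camera adjusted p = 0.046, adjusted p = 0.413 with an estimated correlation). In both lists 0 members passed in limma over all genes or adjusted over the list alone, Stmn1 (-0.045, adjusted p = 0.541) and Xbp1 (-0.047, adjusted p = 0.499) having the smallest p. Of the 30 lists these 2 shifted, 0 did so with an estimated correlation and 0 with fry (4 at an unadjusted p under 0.05 with each). Immediate-early genes did not shift (camera adjusted p = 0.051), and Grm4 (0.11, adjusted p = 0.058) and Crh (0.28, adjusted p = 0.064) came nearest among the other list members. Without the array labelled mutant 27 the clock and immediate-early lists were lower with activity (camera adjusted p = 0.037 each, adjusted p = 0.218 and 0.108 with an estimated correlation). Grm4 (0.11, adjusted p = 0.044) and Crh (0.28, adjusted p = 0.022) passed there.

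The contrast of higher-activity minus lower-activity mutants gave 8 genes, 4 up and 4 down, with H1f2 at 0.32 (adjusted p = 0.0016), Arntl at 0.27 (adjusted p = 0.0038) and Batf3 at -0.42 (adjusted p = 0.013). Within the lower side the slope of Arntl was 0.30 (SE 0.20) and within the higher side 0.076 (SE 0.063), and Id4 fell within the higher side by 0.22 (SE 0.057) without passing (adjusted p = 0.542). Ednrb (-0.20, SE 0.064), Fam107a (0.14, SE 0.055) and Acot11 (0.12, SE 0.058) had slopes there as large as over all mutants. The slopes within the higher side include the array labelled mutant 27. It lay low on that side in activity (46297) and highest on it for Id4 (10.71). Slopes of these genes within that side without this array are not given. None of the 12 genes passed within either side, where the errors of the slopes were larger. Within the lower side 1 gene passed, 4933433H22Rik (-0.97, SE 0.17, adjusted p = 0.035), chosen after its value was seen, and 2215 had an unadjusted p under 0.05. That count was 0 without mutant 1, 2, 9, 21, 28, 29, 31, 33 or 36, 2 without mutant 3, 18 or 30, 3 without mutant 4, 5, 10, 13 or 35, 4 without mutant 6 or 7, and 6 without mutant 11 or 22. Within the higher side 0 genes passed in limma and 1657 had an unadjusted p under 0.05.

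Expression of all genes predicted the activity of a left-out mutant in part. It accounted for 17.9% of the variance of log2 activity (permutation p = 0.0198, highest of 100 permutations 24.2%), and 78.0% of pairs across the gap were ordered correctly (permutation p = 0.0099, the smallest that these permutations can give). This depended on the penalty, since with one 10 times larger the share was 0.677% (permutation p = 0.277) and 22.6% of pairs were ordered correctly (permutation p = 0.594). The 3 arrays labelled wild type, with recorded activity no higher than 20979.78, were predicted at 42233, 35366 and 42604. The lower-activity mutants were predicted at 34523 to 44629 and the higher-activity mutants at 38337 to 50080, so wild type 1 and the array labelled wild type 3 lay within both ranges and wild type 2 within the lower one.

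Age, at matched activity, was followed by Igfbpl1 alone. This gene of newborn neurons fell by 0.097 per week (SE 0.011, adjusted p = 7.3e-07), and 1077 genes had an unadjusted p under 0.05. Other genes of young neurons did not pass, Sox11 (-0.026, adjusted p = 0.228), Sox4 (-0.028, adjusted p = 0.262) and Dcx (-0.046, adjusted p = 0.413) among them. With runs of 8 as a block 126 genes varied with age, 67 up and 59 down, and Sox11 (adjusted p = 0.011), Sox4 (adjusted p = 0.0022) and Dcx (adjusted p = 0.0030) fell. The count was 5 without the array labelled mutant 27 and 2 without mutant 19. Samples within each run of 8 stand in order from oldest to youngest. Age can therefore not be told apart from place within a run, with or without the block.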

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

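All tests of explanations in this part were chosen only after the result was seen, and the regroupings of samples were planned.

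The slope on activity differed between the higher-activity and the lower-activity mutants for 3 genes by a test of the difference itself. For 4933433H22Rik the slope was 0.97 higher on the higher side (SE 0.18, adjusted p = 0.039), from -0.97 to 0.0021 log2 units per doubling. For Il12b, a cytokine subunit, it was 1.08 higher (SE 0.21, adjusted p = 0.047), from -1.05 to 0.036. For Ovgp1, an oviduct glycoprotein, it changed by -2.28 (SE 0.43, adjusted p = 0.039), from 2.08 to -0.20. Without the array labelled mutant 27 none of the 3 passed (adjusted p = 0.056, 0.068 and 0.064), with differences of 0.99, 1.08 and -2.26. Of 10092 probe sets that name no single gene, which the comparisons of genes leave out, 80 differed between the genotypes, 53 higher and 27 lower, and 755 did so without the arrays labelled mutant 27 and wild type 3. Among mutants 4 of them varied with activity.

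The array labelled mutant 27 had the wild-type profile and the array labelled wild type 3 the mutant profile, on genes chosen without either array. On a scale from 0 (wild type) to 1 (mutant), centred within runs, the array labelled mutant 27 lay at 0.201 and the array labelled wild type 3 at 1.04. The other mutants lay at 0.825 to 1.09 and wild types 1 and 2, each held out, at 0.057 and 0.447. Without centring, the array labelled mutant 27 lay at 0.263 and the array labelled wild type 3 at 1.09. The other mutants then lay at 0.764 to 1.11, wild type 1 at 0.108 and wild type 2 at 0.584, nearer to the mutants. Each held-out wild type was placed with 1 other wild type alone, which makes its position less certain. On the array labelled wild type 3, mixed RNA was argued against by Dsp, at most 0.952% of the level of wild types 1 and 2. The share is an upper limit, since Dsp there (3.31) lay with the other mutants (3.26 ± 0.36, SD), near the lower end of all values. The array labelled mutant 27 was not tested for mixed RNA. Both arrays belong to run 4 of the runs of 8 and stand next to each other in sample order. True exceptions with correctly labelled genotypes cannot be told apart from an exchange, since Camk2a, which lay on the other group's side on 2 of the 2 arrays, is what drew attention to them. The recorded activity of the array labelled wild type 3 (14301.12) was the lowest of all 40 and that of the array labelled mutant 27 (46297.38) lay on the higher side, where no wild type lay. Exchanged labels may be the source, as a hypothesis found and tested on the same data. The exchange would then have left the activity with the label, and no array was moved to another group.

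Among mutants 12 genes varied with activity, Arntl among them. Differences between runs were argued against, since 12 of the 12 passed with runs of 8 as a block, and so was the array labelled mutant 27, since 12 of the 12 passed without it. Sampling at different hours of the day could move Arntl against Dbp, Tef and Per2 within each side of the gap, and this held in 1 of the 2 sides. It cannot be told apart from an effect of activity, the hour not being given. With runs and activity removed, r was -0.720 (permutation p = 4e-04, adjusted p = 8e-04) and rho -0.689 (permutation p = 0.00112) over 20 higher-activity mutants, the array labelled mutant 27 being left out, and r was -0.632 without the 2 farthest. Over 16 lower-activity mutants r was -0.448 (permutation p = 0.082, adjusted p = 0.082) and rho -0.244 (permutation p = 0.362), and r was -0.077 without the 2 farthest.

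Mature granule cell markers such as Dsp, Tdo2 and Calb1 were lower in mutants. A lower share of granule cells would raise the markers of all other cell types, and without the 2 doubted arrays 2 of 7 such lists had a mean below 0 by more than 2 standard errors over animals. These were microglia (-0.34, SE 0.068, camera adjusted p = 6.7e-04, adjusted p = 0.170 with an estimated correlation) and endothelium (-0.19, SE 0.081, camera adjusted p = 0.177), and 3 of 7 medians lay so in a first version with errors over list members. Markers of these 2 cell types could fall independently of granule cells, so the test does not decide the share of granule cells. Tissue of neighbouring hippocampal fields in the wild-type samples would lower CA pyramidal markers in mutants, and 4 of 13 passed and were lower, while the list fell (median -0.61, camera adjusted p = 0.012, adjusted p = 0.339 with an estimated correlation). Such tissue would by itself dilute granule cells in wild types and so act against the fall of granule markers. The mean of the 15 granule markers was lower in mutants (-1.07, SE 0.056 over animals, median -0.27), with 6 lower and 4 higher. It was also tried as a test, but only restates the pattern. By itself such tissue would therefore not lower these markers in mutants, while for the CA markers it stays open. A change within granule cells caused by the mutation and a lower share of these cells may both remain. Each is a hypothesis that rests on the labels of 2 doubted arrays and on 2 other wild types.

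Of 100 regroupings of the 40 arrays into 37 and 3, the real one included, 4 gave as many genes as the genotype comparison (719, highest other 6510). For matched activity 4 did so (654, highest other 6706), so that both lay just under the planned limit of 5 in 100. The regroupings ignored the runs, so chance is not taken as excluded. The genotype count was also 0 without wild type 1 and 0 without wild type 2, but both of these fits kept the array labelled wild type 3. The grouping with the highest count, several times the real one, set apart mutant 4, wild type 1 and mutant 6. All 3 are of the first run of 8, which points to the run structure of the samples. With runs as a block it gave 826 genes against 1363 for the real grouping (2 of 100 as large, highest other 2021). The other of these 2 set apart wild type 1, the array labelled mutant 27 and mutant 37, and thus held 2 arrays with the wild-type profile (914 genes without the block). For the list tests chance was not excluded, with 7 of 100 as large for genotype (10 lists, highest other 14) and 16 of 100 at matched activity (8 lists, highest other 14). For activity 1 of 100 was as large (12 genes, highest other 1) and for age 1 of 100 (1 gene, Igfbpl1, highest other 0). Both lay under the planned limit, in regroupings that ignored the runs. Chance was not excluded within the lower side (7 of 100, 1 gene, highest other 800) or for the lists with activity (75 of 100, 2 lists, highest other 16). Within the higher side 0 genes passed (1657 at an unadjusted p under 0.05 in limma), so that 100 of 100 were as large whatever the data (highest other 40), and the test decides nothing.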

How the results depend on the processing

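Settings that leave out the array labelled mutant 27, alone or with the array labelled wild type 3, or each mutant in turn, were chosen after seeing the data. So was the prediction from values centred within runs. The others, leaving out each single wild type among them, were planned. With 3 wild types the genotype counts changed with each one left out. Leaving out wild type 1 or 2 keeps the array labelled wild type 3, which had the mutant profile, as 1 of 2 wild types. Genotype calls (719) were 0 without wild type 1 (956 genes at an unadjusted p under 0.05 in limma), 0 without wild type 2 (1744) and 2360 without the array labelled wild type 3, and at matched activity (654) they were 0 (908 unadjusted), 1 and 2243. Over every animal left out in turn the ranges were 0 to 2360 and 0 to 2243. For the lists shifted by genotype (10) the counts were 6, 1 and 8 without wild type 1, 2 and 3, a range of 1 to 8.

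Genotype and matched-activity counts were 5475 and 4949 with arrayWeights, 1363 and 1211 with runs of 8 as a block, and 235 and 160 at an adjusted p under 0.01. Without the 2 doubted arrays they were 2604 and 2477, and with runs as a block as well 3631 and 3566. The cause of the rise with arrayWeights was not tested. With replicates 1 to 3 of each group only, the count was 0 with the replicate number as a block (2615 unadjusted) and 0 without it (2794 unadjusted), with fewer samples. Deviations of equally numbered mutants and wild types correlated at 0.029, 0.052 and 0.044, so the numbers do not pair the samples. Under the others the counts stayed within 1.5 times, at 484 to 776 and 507 to 709.

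Genes varying with activity (12) numbered 44 with arrayWeights, 44 with runs of 8 as a block, 19 without the 2 farthest mutants, 26 without the array labelled mutant 27 and 98 without that array and with runs as a block. Leaving out each mutant gave 10 to 26, and mutant 27 was the only one to move the count over 1.5 times. The other settings gave 8 to 18. Within the lower side (1 gene) 3 genes passed when that side was fitted alone, and leaving out each mutant gave 0 to 6. Within the higher side 0 genes passed in limma under each setting (1461 unadjusted when fitted alone). Genes varying with age (1) numbered 126 with runs as a block, 5 without the array labelled mutant 27, 237 with both, and 1 to 5 with each mutant left out (2 without mutant 19). Lists numbered 3 with an estimated correlation and 6 with fry for genotype (10), and 1 with an estimated correlation at matched activity (8). For activity (2) they were 0 with an estimated correlation, 0 with fry (4 unadjusted with each), 5 for the contrast across the gap and 5 without mutant 27. The predicted share of variance (17.9%) was 0.677% with a penalty 10 times larger (permutation p = 0.277) and 41.2% with one 10 times smaller, 31.8% from the genes with higher means, 19.7% without mutant 27 and 33.4% with values centred within runs.

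Gene values were followed for the named genes past the threshold and the fixed granule cell genes. The settings with all probe sets, a threshold of 0.01 or each mutant left out in turn were not part of this. No named gene past its threshold changed direction under the settings followed. Dsp (3.44) and Tdo2 (2.98) in mutants lay near the lower end of all values (1.67), which limits the fall an array can show. Dcx reversed to -0.10 with replicates 1 to 3, with and without the block, and to -0.012 without wild type 1 (-0.012 to 0.57 over the wild types), and Calb2 to -0.0078 without wild type 2 (-0.0078 to 0.32). On activity Calb1 reversed to -1.5e-07 on untransformed activity, -0.00080 on ranks and -0.0048 without mutant 27, and Tdo2 to 0.047 across the gap, all far from passing. Besides these reversals, 596 of the values followed kept their side of the threshold, 232 no longer passed and 3 newly passed for genotype. At matched activity 550, 114 and 6 did so, and for activity 222 kept it and 6 no longer passed.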

Other observations

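The tests of lists and of the neighbours of Camk2a in this part were chosen only after the data were seen, and values of single genes come from the planned comparisons.

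Some genes of cholesterol synthesis and its control rose in mutants. Of 23 such genes 20 were measured, 5 rose, 0 fell and 15 did not pass in limma (median 0.27). Stard4, a cholesterol carrier, rose by 0.86 (SE 0.16, adjusted p = 0.0033, higher than the wild-type mean in 36 of 37 mutants) and Tmem97 by 0.68 (SE 0.12, adjusted p = 0.0033). Sqle rose by 0.55 (SE 0.12, adjusted p = 0.0055), Fdft1 by 0.57 (SE 0.14, adjusted p = 0.016) and Hmgcs1 by 0.47 (SE 0.11, adjusted p = 0.0081). Without the arrays labelled mutant 27 and wild type 3, 12 of the 20 rose. The list was made after these genes were seen among the calls, so its test decides nothing (adjusted p = 0.071 with an estimated correlation, and 0.0094 without the 2 arrays).

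Among mutants, markers of young neurons were lower in older animals. Of 15 immature neuron markers 1 fell with age, Igfbpl1, and 6 fell when adjusted over the list alone (median -0.015 per week, camera adjusted p = 2.1e-09, adjusted p = 0.0011 with an estimated correlation). Proliferation genes were lower as well (median -0.015 per week, camera adjusted p = 4.5e-04, adjusted p = 0.018 with an estimated correlation). Microglia markers were higher (median 0.013, camera adjusted p = 7.1e-05, adjusted p = 0.107 with an estimated correlation). In all 13 of 30 lists shifted with age, 10 up and 3 down, and 2 did so with an estimated correlation. No regroupings were run for the lists with age, while regrouped activity among the same mutants gave up to 16 lists, so chance was not excluded.

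Of the 60 genes nearest to Camk2a in gene order, 15 differed between the genotypes without the 2 doubted arrays, 25.0% against 14.3% of all genes. Of 16935 windows of that size, 4.28% held as many.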
